A study of Homo sapiens with 12 samples.

How the data were processed

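HCT116, an established human colon cancer cell line, was studied in an engineered form without MTAP (MTAP-null) and a form that keeps MTAP (MTAP-WT). MTAP is the phosphorylase that recycles methionine from methylthioadenosine. Both forms were treated with AGI24512, which the labels describe as an inhibitor of MAT2A, the enzyme that makes S-adenosylmethionine, or with the solvent DMSO. Each of the 4 groups had 3 libraries, 12 in all, grouped by their titles, genotype and treatment labels. RNA was enriched for poly-A and sequenced as paired ends on a HiSeq instrument, per the labels. The labels give no dose or duration. They do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

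Only tables of the authors' own splicing comparisons were analysed, with 6 tables per genotype. The intron table was made with DEXSeq, per the file headers, which tests how much of a gene's signal falls in a feature. It holds 1549 features for MTAP-null and 258 for MTAP-WT, and each carries the name of a detained intron, an intron that stays in a polyadenylated nuclear transcript. Of these, 158 MTAP-null and 43 MTAP-WT features also carry the name of an annotated transcript, so they can lie in an exon. They are called introns below all the same. The highest adjusted p-value in the authors' deposited table was 0.0499 for MTAP-null and 0.0494 for MTAP-WT, so features that did not pass were not analysed here. The deposited raw read counts per feature and library, per the file headers, are whole numbers that the authors did not normalize. The deposited signal in the column of base means is the mean of counts divided by size factors, per the file headers and a test on the values. A score per group in the authors' tables is the fitted usage on the variance-stabilised scale of DEXSeq. The deposited log2 fold is the log2 of DMSO over AGI24512 usage, and its sign was turned here so that a positive value is higher with AGI24512. It is not a fold of counts.

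The other 5 tables per genotype were made with rMATS, per the file headers, and hold skipped exons (SE), retained introns (RI), alternative 3' splice sites (A3SS), alternative 5' splice sites (A5SS) and mutually exclusive exons (MXE). Their deposited score is the inclusion level of sample set 1 minus that of set 2, with the authors' p-value and FDR. All listed events had an FDR under 0.05. The headers do not say which treatment is set 1, so rMATS directions are given as set 1 or set 2, levels as the range over the libraries of a set, and no mean or SD is given. Some cells of read counts had lost their separators, and these counts were used only as a lower bound for a filter at 20 reads per library. The aligner, tool versions and genome build are not given in the sources used here. Coordinates were compared with the GENCODE 29 annotation of GRCh38: 852 of the 1549 MTAP-null features and 119 of the 258 MTAP-WT features matched an annotated intron exactly. No genome sequence was used, so GC content was not analysed here.

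Usage values below are the authors'. Read counts were tested separately with edgeR 4.0.16 (quasi-likelihood, R 4.3.3), AGI24512 against DMSO within a genotype, with Benjamini-Hochberg adjustment over the listed features. Each fit also pools information on the spread over its own features. Its p-values and calls are therefore not on the same scale in the 2 genotypes. The size factors were those recovered from the deposited base means, and lay between 0.859 and 1.14 in MTAP-null and between 0.953 and 1.09 in MTAP-WT. "Rose" and "fell" refer to this test of the read count, while "higher usage" and "lower usage" refer to the authors' table. A change of the read count mixes a change of the gene's RNA with a change of the intron's share. The features were chosen by the authors on the same libraries, so counts of calls describe the list and are not independent evidence. The counting of reads in overlapping or antisense genes, and the use of strand, are not given in the sources used here. A feature with the symbols of 2 genes (77 in MTAP-null and 15 in MTAP-WT) was kept out of lists and of the genes named by rule. The 92 introns listed in both genotypes were also fitted in 1 model over all 12 libraries with a drug-by-genotype term. DESeq2 1.42.0 was the other tool.

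The edgeR step was tested on simulated counts drawn from these means. Of features changed by 1 on the log2 scale it recovered 72.9% over the 1549 MTAP-null features and 85.7% over the 258 MTAP-WT features. At a change of 2, it recovered 99.0% and 97.7%. It made 9 false calls among 1349 unchanged MTAP-null features and 4 among 158 in MTAP-WT. The drug-by-genotype step recovered 76.7% of changes of 1 over 92 features, with 0 false calls among 62. In these simulations the tested changes were drawn in both directions alike, most features had none, and the true size factors were given. They thus do not test the scaling between libraries, or a list chosen on the same libraries in which most introns rise.

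Splits into higher and lower were tested with exact two-sided binomial tests, and shares with Fisher's exact test. Introns and genes are not replicates, so those p-values describe the lists. Lengths of increased and decreased introns were compared with a permutation test of 100000 resamples. Gene lists were compared with all annotated protein-coding genes with more than 1 exon, which does not control for expression. For the intron tables it also does not control for which genes have an intron named as detained. There were 16 lists: crosslink repair and homologous recombination, damage signalling and other DNA repair, DNA replication, mitosis, the p53 pathway and apoptosis, splicing regulators (SR proteins and hnRNPs), the core spliceosome, splicing kinases, methionine and polyamine metabolism, arginine methyltransferases, RNA modification, chromatin regulators, nonsense-mediated decay and mRNA export, cytosolic ribosomal proteins, ZNF genes and aminoacyl-tRNA synthetases. Symbols matched the annotation for 1132 of 1230 MTAP-null and 202 of 221 MTAP-WT genes of the intron tables, and for 307 of 357 and 59 of 73 genes with rMATS events. In 20 simulated draws of genes, 2 of 320 list tests passed without a signal and a planted list passed in 20 draws. In the tests of intron position and of exon frame at 20 reads, the form of the test was chosen after the data were seen.

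The lists, the main tests and the rule for named genes were chosen before the data were examined. The rule took, per genotype, the introns with the largest increase or decrease in usage in the more abundant part of the table, 1 per gene (8 and 5 in MTAP-null, 4 and 3 in MTAP-WT), and the largest rMATS differences per class. It added the 5 shared introns with the largest MTAP-null effect, the 4 members of each list with the smallest adjusted p, and 10 genes always looked up. Named genes outside the rule are said to be chosen after their values were seen. Alternatives were stricter thresholds, a minimum change of 1 on the log2 scale, the more abundant features, genes in place of features, a filter at a mean count of 10, TMM scaling on the listed introns, DESeq2, other definitions of overlap, a replicate block, and leaving out each library. TMM assumes that most features did not change. The introns were listed as changed, so TMM lowers them about alike, and a call lost or turned under it says nothing about a single gene. Libraries of a group were compared in pairs over all features: the chi-square per degree of freedom was between 1.43 and 5.12, all above 1, and no pair was treated as a duplicate. Replicate 1 stood apart in 3 groups: MTAP-null AGI24512 (3.39 and 5.12, against 1.57 for the other pair), MTAP-WT AGI24512 (4.09 and 2.80 against 1.52) and MTAP-WT DMSO (3.77 and 3.54 against 1.45). Every count column was mapped to a library.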

Results

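The data are tables of splicing changes in HCT116 cells, an established human colon cancer line, with or without the MTAP gene, after AGI24512 or the solvent DMSO. AGI24512 is described as an inhibitor of MAT2A, the enzyme that makes S-adenosylmethionine, the methyl donor used by RNA and protein methyltransferases. The design asks how the compound acts in cells that lack MTAP, and the MTAP-WT form of the line is the counterpart. Each of the 4 groups had 3 libraries. Summed counts over the listed introns ranged from 113064 to 214530 per MTAP-null library and from 50919 to 65080 per MTAP-WT library. These sums cover only features that passed the authors' test and are not the sequencing depth, which is unknown here.

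In MTAP-null cells, the listed introns mostly took a larger share of their gene's reads with AGI24512. The authors' deposited table listed 1449 features with higher usage and 100 with lower usage, an increased share of 93.5% (exact two-sided binomial p = 4.50e-307). By gene, 1208 of 1287 had higher usage in the authors' deposited table. Read counts followed: edgeR called 1202 of the 1549 introns as risen and 72 as fallen. The median log2 change of the read count was 0.99 among the introns with higher usage and -0.44 among those with lower usage.

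Among the more abundant introns, the largest gains in usage included SNHG5 and SNHG1, non-coding genes that host small nucleolar RNAs. The SNHG5 intron (chromosome 6, 85677493 to 85677790, internal) had a usage log2 change of 1.33 in the authors' deposited table, adjusted p = 1.77e-42. Its normalised count was 115.3 ± 18.4 with AGI24512 and 47.6 ± 6.09 with DMSO (SD, n = 3). That is a 2.42-fold difference, with a log2 change of 1.27, a standard error of 0.21 and edgeR adjusted p = 0.000181. The SNHG1 intron (chromosome 11, 62854065 to 62854518, internal) had a usage change of 1.10 in the authors' deposited table. Its read count did not differ beyond the replicate spread, with a log2 change of -0.04 (edgeR adjusted p = 0.876), 0.24 without AGI24512 replicate 1, and a fall of the read count, at -0.91, with TMM scaling.

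TRPM4, a calcium-activated cation channel, had the strongest rise in read count of this set, from 32.7 ± 4.51 to 160.7 ± 17.1 (SD, n = 3), or 4.92-fold (edgeR adjusted p = 1.2e-06), in an internal intron on chromosome 19, 49158260 to 49166040. CPNE7, a calcium-dependent membrane-binding copine, rose 4.57-fold in a feature on chromosome 16, 89592292 to 89593965, from 27.4 ± 10.1 to 125.1 ± 11.05 (SD, n = 3; edgeR adjusted p = 8.75e-06). TARBP1, an RNA methyltransferase, rose 3.21-fold, IFRD1, a transcriptional coregulator, 2.40-fold, and SERPINF1, a secreted antiangiogenic protein, 2.13-fold. SAT1, which acetylates spermidine and spermine, rose 1.81-fold (edgeR adjusted p = 0.00423), but its libraries overlapped between groups. With TMM scaling, which lowers all listed introns about alike, its log2 change was -0.02.

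Lower usage was led by GOLGA4, a tethering protein of the trans-Golgi. Its internal intron on chromosome 3, 37273602 to 37281957, fell from 200.6 ± 26.7 to 96.8 ± 13.9 normalised counts (SD, n = 3), with a log2 change of -1.05, a standard error of 0.17 and edgeR adjusted p = 0.00022. MDN1, an ATPase of large ribosomal subunit assembly, fell further, from 957.5 ± 55.4 to 282.4 ± 37.7 (SD, n = 3), with a log2 change of -1.76 and edgeR adjusted p = 2.82e-08 (chromosome 6, 89719228 to 89722954). MTHFD1, a folate enzyme that feeds the methionine cycle, had a log2 change of -0.95, KRT8, a keratin of simple epithelia, one of -0.77, and the nucleolar protein gene GPATCH4 one of -0.51. The GPATCH4 call was lost without AGI24512 replicate 2, DMSO replicate 2 or DMSO replicate 3, and in DESeq2. The KRT8 feature also lies in an exon of an annotated transcript.

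Of the introns with higher usage, 1169 (80.7%) had all AGI24512 libraries above all DMSO libraries, and 66 of the 100 with lower usage had them all below. Chance gives 10% once the direction is known, but the introns were chosen on the same libraries, so a high share is built in. The DEXSeq test compares an intron with the rest of its gene, but the edgeR counts depend on the scaling between libraries. TMM scaling on the listed introns moved the median log2 change from 0.95 to 0.11. It gave 251 introns that rose and 253 that fell. SNHG5, IFRD1 and SERPINF1 then had log2 changes of 0.44, 0.42 and 0.24 without a call. TMM lowers the listed introns about alike by construction, so calls lost or turned under it in these Results say nothing about single genes.

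**Figure D1:**
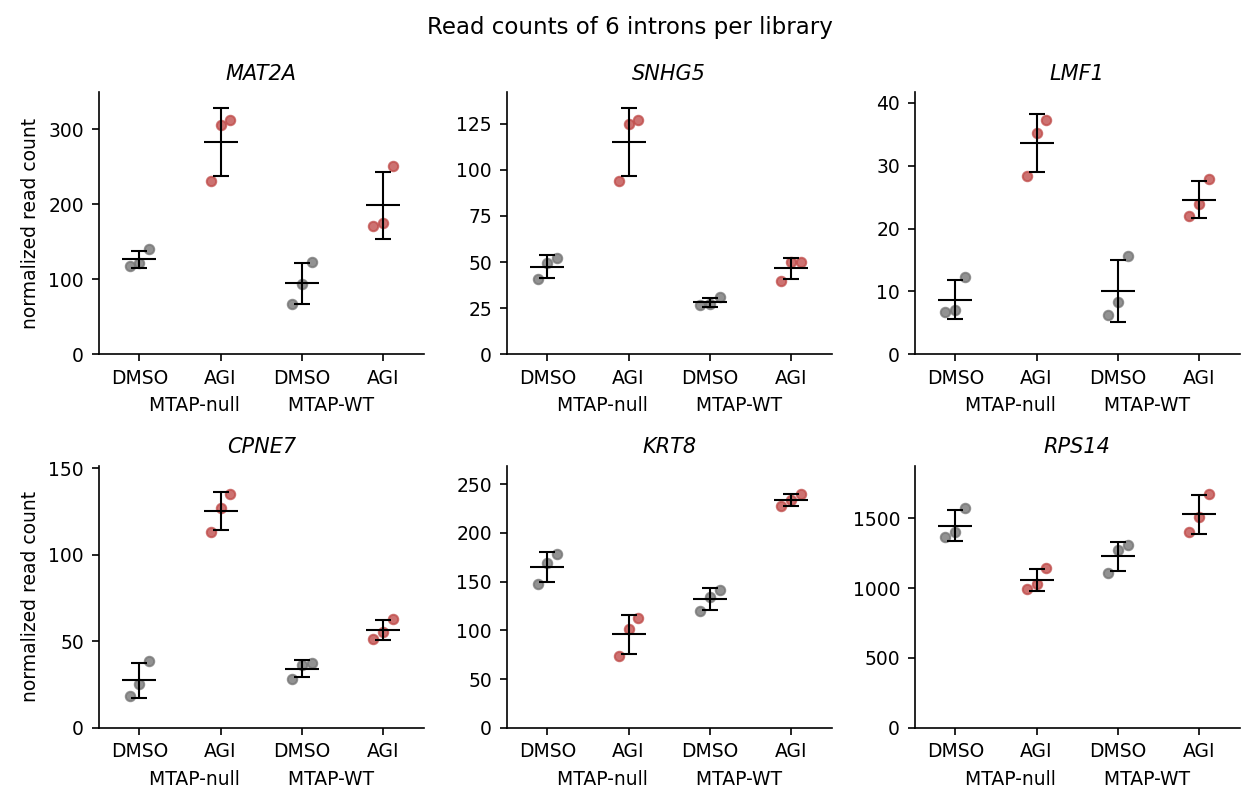
Normalised read counts (vertical axis, from 0) of 6 introns listed in both genotypes, with 1 point per library, a horizontal mark at the mean and bars of 1 SD over 3 libraries; grey points are DMSO and red points AGI24512. MAT2A, SNHG5, LMF1 and CPNE7 were higher with AGI24512 in both genotypes, and KRT8 and RPS14 were lower in MTAP-null and higher in MTAP-WT; with TMM scaling on the listed introns the RPS14 change in MTAP-WT turned to -0.25 on the log2 scale.

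Splicing regulators were over-represented among the MTAP-null genes, relative to all coding genes. SR proteins, hnRNPs and related factors set splice-site choice, and 14 of the 80 list members had a listed intron, against 6.0% of background genes (Fisher's exact test, odds ratio 3.35, adjusted p = 0.00422). Their 19 introns comprised 16 that rose and 3 that fell by edgeR, and the same numbers adjusted over the list alone. With TMM scaling 1 rose and 3 fell. HNRNPUL1 rose 1.98-fold in its first intron (chromosome 19, 41265344 to 41268222), from 66.6 ± 0.637 to 131.5 ± 37.0 (SD, n = 3), and RBM39 rose 1.86-fold. With TMM scaling their log2 changes were 0.12 for HNRNPUL1 and 0.04 for RBM39, without a call. RBM5 rose 1.53-fold, but its log2 change turned to -0.22 with TMM scaling and its call was lost without DMSO replicate 1. SRSF10 fell to 0.317 of its DMSO count in a feature of 3 bp that lies in an annotated exon (chromosome 1, 23975078 to 23975080).

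Genes of nonsense-mediated decay and mRNA export were also over-represented, with 8 of 49 members (odds ratio 3.07, Fisher's exact test, adjusted p = 0.0438). Of their 8 introns, 5 rose and 0 fell (3 did not pass), and the counts adjusted over the list alone were 5 and 0. With TMM scaling 2 rose and 1 fell. EXOSC9, a subunit of the RNA exosome, rose 3.43-fold (chromosome 4, 121816195 to 121816368), NUP107, a nuclear pore scaffold protein, 4.41-fold, and EXOSC10 2.502-fold, in a feature that lies in an annotated exon and lost its call with TMM scaling. ZNF genes, a family of zinc-finger transcription factors, were under-represented, with 17 of 513 (odds ratio 0.53, adjusted p = 0.0438). Their 19 introns comprised 16 that rose and 0 that fell, 16 and 0 adjusted over the list alone, and 6 and 1 with TMM scaling. ZNF250 lost its call without AGI24512 replicate 2 or 3 or DMSO replicate 2. No list passed when only features with an adjusted p below 0.01 (lowest adjusted p = 0.139) or only increased features (lowest 0.086) were used, although the odds ratios were then 2.90 and 2.66 for splicing regulators, 2.95 and 2.78 for decay and export, and 0.51 and 0.56 for ZNF genes. The background does not control for expression. Every listed feature carries the name of a detained intron, while the background is all coding genes. These odds ratios may thus reflect which genes have such introns, and the drug cannot be told apart from that.

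Mitosis genes did not pass, with 12 of 94 members (odds ratio 2.31, Fisher's exact test, adjusted p = 0.0533), and with 5 at an adjusted p below 0.01 (odds ratio 1.46, adjusted p = 0.612). All 13 of their introns rose, also adjusted over the list alone; with TMM scaling 5 rose and 0 fell. CDK1, the kinase that drives entry into mitosis, rose 7.61-fold, from 10.8 ± 2.59 to 82.0 ± 27.7 (SD, n = 3; edgeR adjusted p = 8.75e-06; chromosome 10, 60787070 to 60788059). Kinetochore genes SPC24 and NDC80 rose 3.62-fold and 2.87-fold. The repair and replication lists did not pass: crosslink repair had 5 of 45 members (adjusted p = 0.296), damage signalling 7 of 64 (0.214) and DNA replication 7 of 58 (0.194). In a table where 1202 of 1549 introns rose, all 8 introns of crosslink repair and all 9 of damage signalling did, and replication had 6 that rose and 1 that fell, each the same adjusted over the list alone. FANCL, a ubiquitin ligase of crosslink repair, rose 2.23-fold, TOPBP1, an activator of ATR, 4.80-fold, and the ribonucleotide reductase subunit gene RRM1 5.51-fold, while XRCC3, TP53BP1, RECQL4 and DCLRE1C rose 1.49-fold to 1.73-fold and turned to between -0.05 and -0.28 on the log2 scale with TMM scaling. Calls were also lost without DMSO replicate 1 (XRCC3 and RECQL4, XRCC3 without 3 other libraries too) or DMSO replicate 2 (DCLRE1C). BARD1, of the crosslink repair list, lost its call without AGI24512 replicate 2 or 3 or DMSO replicate 1 or 2, and in DESeq2. FANCL lost its call with TMM scaling. Without DMSO replicate 1 the TOPBP1 log2 change moved from 2.20 to 2.98. With that scaling 0 of the 8 crosslink repair introns, 1 of the 9 damage signalling introns and 1 of the 7 replication introns rose.

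Methionine and polyamine genes had 6 of 44 members listed (adjusted p = 0.148), with 4 introns that rose, 2 that fell and 2 that did not pass, the same adjusted over the list alone and 1 and 4 with TMM scaling. OAZ1, the antizyme that limits polyamine synthesis, rose 2.79-fold. Aminoacyl-tRNA synthetases had 5 of 36 members (adjusted p = 0.166; 6 of 6 introns rose, 1 with TMM scaling), led by CARS2 at 2.32-fold and LARS at 2.23-fold. Chromatin regulators had 9 of 113 members (adjusted p = 0.399; 8 of 9 introns rose, and 2 rose and 1 fell with TMM scaling), among them KDM2B at 4.40-fold and SMARCC1 at 3.59-fold. RNA modification genes had 4 of 42 members (adjusted p = 0.399; 4 of 4 introns rose, 0 with TMM scaling), with TRMT1, a tRNA methyltransferase, at 3.82-fold. The splicing kinases had 3 of 21 members (adjusted p = 0.228; 5 of 5 introns rose, 0 with TMM scaling), with CDK10 at 1.995-fold. With TMM scaling the log2 changes were 0.38 for CARS2, 0.31 for LARS, 1.01 for TRMT1 and 0.13 for CDK10, without a call. METTL4 lost its call without AGI24512 replicate 2 or 3 or DMSO replicate 1 or 2, and in DESeq2. YTHDC1 lost its call without AGI24512 replicate 3 or DMSO replicate 2. CLK2 lost its call without AGI24512 replicate 3 or DMSO replicate 2 or 3. CLK3 lost its call without DMSO replicate 1 or 2, and WARS2 without DMSO replicate 1. KAT8 lost its call without AGI24512 replicate 2 or 3 or any DMSO replicate, with the replicate block and in DESeq2.

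The core spliceosome had 7 of 99 members (adjusted p = 0.763), of whose 7 introns 4 rose and 0 fell, and 0 rose and 3 fell with TMM scaling; STRAP, a factor of snRNP assembly, rose 2.83-fold, a call lost with TMM scaling. The p53 and apoptosis list had 2 of 52 members (adjusted p = 0.816), and FAS, a death receptor, rose 3.27-fold, while TNFRSF10B, another death receptor, had a log2 change of 0.21 that did not pass (edgeR adjusted p = 0.282) and fell with TMM scaling, at -0.63. Arginine methyltransferase genes had 2 of 14 members (adjusted p = 0.296): CLNS1A, a cofactor of PRMT5, rose 1.56-fold but turned to -0.19 on the log2 scale with TMM scaling, and FBXO11 had a log2 change of 0.54 that did not pass (edgeR adjusted p = 0.0922), passed without AGI24512 replicate 2, and turned to -0.30 with TMM scaling. Ribosomal protein genes had 5 of 81 members (adjusted p = 0.816), of whose 5 introns 1 rose and 3 fell, the same adjusted over the list alone and 0 and 4 with TMM scaling. Among them RPS14 fell by 0.45 and RPL15, in a feature that lies in an annotated exon, by 0.33 on the log2 scale. The list was drawn by symbols of RPL or RPS and a number, which leaves out the ribosomal protein gene RPLP0. The RPLP0 feature had lower usage and a read count log2 change of -1.41 (standard error 0.083) in MTAP-null. For the lists of this paragraph and the one before, the counts adjusted over the list alone were those given.

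MAT2A itself stood out in both genotypes, because its last intron gained reads while its usage went down. In MTAP-null cells the intron (chromosome 2, 85543035 to 85543669) rose from 126.7 ± 11.6 to 282.7 ± 45.1 normalised counts (SD, n = 3), with a log2 change of 1.16, a standard error of 0.16 and edgeR adjusted p = 6.9e-05. In MTAP-WT cells it rose from 94.4 ± 27.8 to 198.7 ± 44.9 (SD, n = 3), with a log2 change of 1.08, a standard error of 0.16 and edgeR adjusted p = 8.56e-10. The 2 fits were separate and pooled the spread over different features, so these p-values do not rank the genotypes. The usage log2 change of the intron was -0.55 and -0.62 in the authors' deposited table. With TMM scaling the change of the read count was 0.31 in MTAP-null, where the call was lost, and 0.51 in MTAP-WT. A feature of MTAP (chromosome 9, 21809001 to 21813765) was listed in MTAP-null only and rose 2.25-fold (not called with TMM scaling), but the labels do not say which part of the gene was removed, so it does not check the genotype. Neither intron nor event was listed for WDR77, FANCA, ATM, AURKB, CLK1 or SRSF2 in either genotype.

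MTAP-WT cells had far fewer listed introns, and these too were mostly increased. The authors' deposited table listed 204 features with higher usage and 54 with lower usage, an increased share of 79.1% (exact two-sided binomial p = 1.09e-21). By gene, 187 of 236 had higher usage in the authors' deposited table. edgeR called 182 introns as risen and 37 as fallen. The median log2 change of the read count was 0.90 where usage was higher and -0.48 where it was lower, and 176 of the 204 (86.3%) and 37 of the 54 had no overlap between the groups' libraries, against 10% by chance for introns not chosen on them.

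UTRN, the dystrophin-related cytoskeletal linker, rose 2.27-fold in an internal intron (chromosome 6, 144828856 to 144835779), from 49.1 ± 8.59 to 111.3 ± 11.98 normalised counts (SD, n = 3; edgeR adjusted p = 5.86e-09). The adhesion receptor gene GPR125 rose 2.29-fold, COA1, a mitochondrial assembly factor, 1.91-fold and TMCO3 1.57-fold. SBF2, a regulator of myotubularin phosphatases, fell from 232.7 ± 29.7 to 100.5 ± 8.63 (SD, n = 3), with a log2 change of -1.21 and edgeR adjusted p = 1.51e-12 (chromosome 11, 9809003 to 9812531). RPS27, a ribosomal protein gene, fell by 0.42 on the log2 scale (edgeR adjusted p = 0.0212), with overlapping libraries, and lost its call without AGI24512 replicate 1, AGI24512 replicate 3 or DMSO replicate 2 and in DESeq2. TMM scaling on the listed introns moved the median log2 change from 0.73 to 0.16 and gave 60 introns that rose and 68 that fell; COA1 and TMCO3 then lost their calls.

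Ribosomal protein genes were the over-represented list in MTAP-WT, with 5 of 81 members against 1.07% of background genes (Fisher's exact test, odds ratio 6.21, adjusted p = 0.0284). Usage was lower at all 7 of their features in the authors' deposited table. Their read counts went both ways: 2 rose and 1 fell by edgeR, 1 and 0 adjusted over the list alone, and 0 and 6 with TMM scaling. RPLP0, left out by the symbol rule of this list, had lower usage and a read count log2 change of -0.50 (standard error 0.11). RPS14 rose 1.25-fold (chromosome 5, 150447474 to 150447584; edgeR adjusted p = 0.00609), which turned to -0.25 on the log2 scale with TMM scaling and lost its call without AGI24512 replicate 2 or DMSO replicate 3. With only increased features the list had 0 members. The background does not control for which genes have an intron named as detained. The other 15 lists had 4 members or fewer (adjusted p of 0.938 or above). Crosslink repair, replication, mitosis, p53, arginine methyltransferase and RNA modification genes had 0 members. ZNF genes had 4, with 3 introns that rose and 1 that fell (2 and 1 with TMM scaling). ZNF638 led at 6.83-fold, and its log2 change of 2.75 moved to 4.30 without DMSO replicate 3 and 2.14 without DMSO replicate 1. The core spliceosome had 2, SNRPE, which fell, and SNRNP27, which rose but turned to -0.20 on the log2 scale with TMM scaling (0 rose and 1 fell). Chromatin regulators had 2 that rose (1 with TMM scaling), TET2 at 5.34-fold, whose log2 change of 2.42 moved to 3.36 without DMSO replicate 2 and 1.80 without DMSO replicate 1, and HDAC7, which turned to -0.03 with TMM scaling. Damage signalling (ERCC8), splicing regulators (RBM5), splicing kinases (CDK13), methionine metabolism (MAT2A), decay and export (NUP214 at 2.41-fold) and tRNA synthetases (RARS2 at 4.05-fold) had 1 each, and all 6 introns rose. With TMM scaling MAT2A and RARS2 kept the call, and ERCC8 turned to -0.06. RBM5, CDK13 and NUP214 then had log2 changes of 0.33, 0.10 and 0.68 without a call. SNRPE lost its call without AGI24512 replicate 3 or DMSO replicate 3, and ERCC8 without any of 4 libraries and in DESeq2. For all lists here other than ribosomal proteins, the counts adjusted over the list alone were the same. The RBM5 and SNRNP27 features lie in an annotated exon.

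The rMATS tables add changes at single exons and splice sites, whose direction is given as sample set 1 or set 2 because the treatment of each set is not stated. In MTAP-null, retained introns (RI) lay mostly on the side of set 1: 44 were higher in set 1 and 7 in set 2 in the authors' deposited table (exact two-sided binomial test, adjusted p = 1.21e-06). Skipped exons (SE) were split evenly, with 134 and 142 (adjusted p = 0.962). Alternative 3' sites (A3SS) were at 18 and 19, alternative 5' sites (A5SS) at 36 and 20 (adjusted p = 0.147) and mutually exclusive exons (MXE) at 24 and 15 (adjusted p = 0.400). In all, 459 events in 357 genes were listed. The 3 levels of set 1 did not overlap those of set 2 in 251 of the 276 skipped exons and 47 of the 51 retained introns, where chance gives 10% for events not chosen on these libraries. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1.

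LUC7L, a partner of the U1 snRNP, had the largest retained-intron difference, 0.69 in the authors' deposited table (chromosome 16, 227337 to 228332), with levels of 0.746 to 1 in set 1 and 0.093 to 0.202 in set 2. UPK3B, a uroplakin, had the largest difference the other way, -0.44 in the authors' deposited table. The largest skipped-exon differences were at CACNB4, a calcium channel subunit (-0.85), and LCA5L (0.82) in the authors' deposited table, with lower bounds of 1.83 and 5.33 reads per library. In all, 71 of the 276 skipped exons had a lower bound under 20 reads. Among other classes, TAB3, an adaptor of inflammatory kinase signalling, had a difference of 0.54 at a 3' site and RHBG, an ammonium transporter, 0.50 at exclusive exons in the authors' deposited table. At 5' sites, the isoleucyl-tRNA synthetase gene IARS had a difference of -0.17 in the authors' deposited table.

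Splicing regulators were over-represented among genes with rMATS events, with 10 of 80 members (odds ratio 8.89, Fisher's exact test, adjusted p = 1.08e-05). These events come from the same libraries as the introns. The background of all coding genes controls neither for expression nor for the number of isoforms of a gene. HNRNPDL, an hnRNP that regulates its own exon use, had a skipped exon (chromosome 4, 82425563 to 82425667) with a difference of -0.26 in the authors' deposited table, at levels of 0.176 to 0.211 in set 1 and 0.423 to 0.498 in set 2. HNRNPA2B1 had a difference of 0.16 and LUC7L3 one of 0.37 at a retained intron in the authors' deposited table. The 17 events of the list comprised 10 higher in set 1 and 7 in set 2. No other list passed at the listing threshold. Damage signalling had adjusted p = 0.163 and methionine metabolism (SHMT2, MTRR and AHCYL2) 0.182, and these became 0.0288 and 0.0488 at an FDR below 0.01. SHMT2, a mitochondrial serine hydroxymethyltransferase, had a skipped exon with a difference of 0.12 in the authors' deposited table, and the apoptosis regulator BCL2L1 a 3' site with -0.19. Counts in the remaining lists were 8 ZNF genes, 4 mitosis, 3 decay and export genes, 2 each for crosslink repair, p53 and ribosomal proteins, 1 each for the core spliceosome, kinases, chromatin and synthetases, and 0 for replication, arginine methyltransferases and RNA modification (adjusted p of 0.182 or above).

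MTAP-WT had 99 events in 73 genes, with skipped exons at 36 higher in set 1 and 25 in set 2, retained introns at 5 and 5, 3' sites at 1 and 8, 5' sites at 6 and 8 and exclusive exons at 1 and 4 in the authors' deposited table (exact binomial tests, adjusted p of 0.147 or above). PRMT5, the arginine methyltransferase of the methylosome, had a 5' site (chromosome 14, 22929167 to 22929251) with a difference of 0.32 in the authors' deposited table, at 0.701 to 0.795 in set 1 and 0.397 to 0.485 in set 2. MDM4, an inhibitor of p53, had a skipped exon (chromosome 1, 204537459 to 204537497) with a difference of 0.31 in the authors' deposited table. Neither gene was listed in MTAP-null. Other large differences were at VIPR1, PRDM8 and AP3M2 exons (0.70, -0.83 and -0.78 in the authors' deposited table), each with a lower bound under 20 reads per library. No list passed by Fisher's exact test (lowest adjusted p = 0.340), and 2 had an unadjusted p below 0.05, mitosis with 2 members and arginine methyltransferases with 1. ZNF genes had 3 members, p53, splicing kinases and methionine metabolism 1 each, and the other 10 lists 0.

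The genotypes were then compared. MTAP-null had 1549 listed introns to 258 in MTAP-WT, a ratio of 6.004, and 4 to 7.80 times as many events by class. The share of each class did not differ between genotypes (Fisher's exact tests, adjusted p = 0.861 for all 5). The share of introns with higher usage was larger in MTAP-null (odds ratio 3.84, Fisher's exact p = 7.01e-12; by gene 4.01), but not among features with a change of at least 1 on the log2 scale (odds ratio 1.38, p = 0.564). A longer list is not a test of a stronger effect, and no gene list separated MTAP-null genes from MTAP-WT genes after adjustment, with ribosomal proteins closest (odds ratio 0.11, adjusted p = 0.0653).

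LMF1, a lipase maturation factor, SNHG5, WWC3, CPNE7 and ZC2HC1A had the largest usage changes in MTAP-null among the 92 introns listed in both genotypes. LMF1 rose 3.88-fold in MTAP-null, from 8.67 ± 3.08 to 33.6 ± 4.68, and 2.45-fold in MTAP-WT, from 10.03 ± 4.91 to 24.6 ± 2.95 (SD, n = 3; edgeR adjusted p = 0.000244 and 0.000249; chromosome 16, 954667 to 964046). ZC2HC1A rose 2.68-fold and 2.12-fold. WWC3, a scaffold of Hippo signalling, rose 3.69-fold in MTAP-null, while its 1.56-fold value in MTAP-WT did not pass (edgeR adjusted p = 0.0557) but did without DMSO replicate 1 or 2. Without DMSO replicate 2 its MTAP-null log2 change moved from 1.84 to 2.91. With TMM scaling LMF1, SNHG5 and CPNE7 lost their calls in MTAP-WT. Usage went the same way at 86 of the 92 introns (exact binomial p = 3.09e-19 against an even split), where the shares of increased introns among them alone would give 63.0 (Fisher's exact p = 7.28e-12), with a Pearson correlation of 0.811 and a Spearman correlation of 0.793 across introns, which are not independent replicates and were chosen by both lists. The shared introns were 35.7% of the MTAP-WT list and 5.94% of the MTAP-null list.

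**Figure D2:**
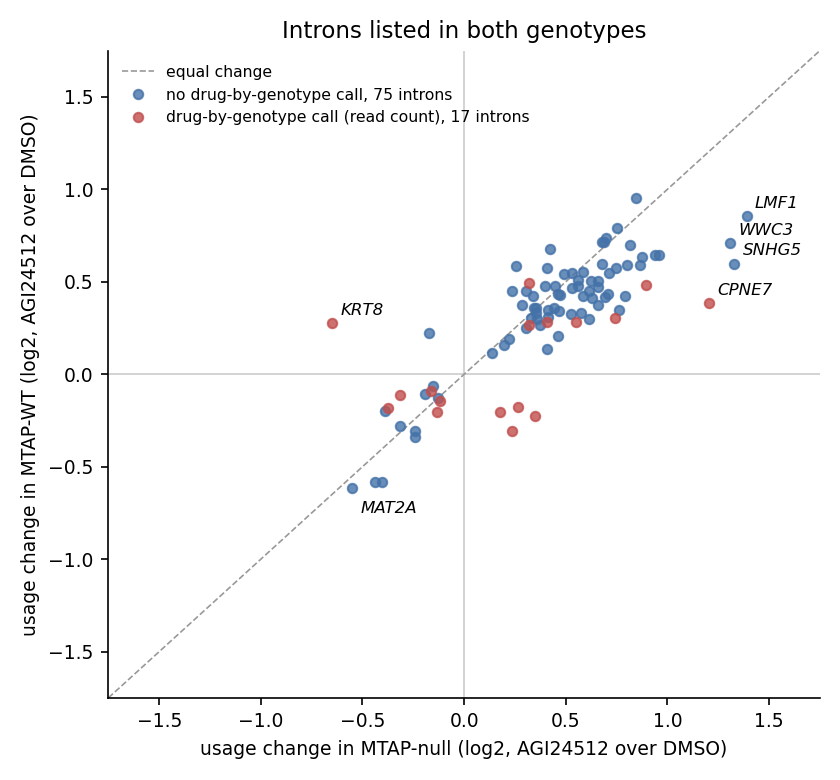
Change in usage (log2, AGI24512 over DMSO, in the authors' deposited table) of the 92 introns listed in both genotypes, MTAP-null on the horizontal and MTAP-WT on the vertical axis, with 1 point per intron and a dashed line of equal change. Of the points, 86 lie in the lower left or upper right quadrants, and the 17 red points had a drug-by-genotype call on the read count.

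The change in usage was larger in MTAP-null at 63 of the 92 shared introns in the authors' deposited table (exact binomial p = 0.000509), with a median difference of 0.08 on the log2 scale. By read count it was larger at 50 of the 92 (exact binomial p = 0.466). The drug-by-genotype test on read counts, in edgeR over all 12 libraries, called 17 of the 92 introns, 9 with the more positive change in MTAP-null and 8 in MTAP-WT. All 92 had passed the authors' test in both genotypes, which leaves out introns that pass in a single genotype. These comparisons thus do not measure how alike the drug effect is over all introns. The CPNE7 difference was 1.48 (edgeR adjusted p = 0.00182). KRT8 fell in MTAP-null and had a log2 change of 0.83 in MTAP-WT (0.25 and no call with TMM scaling), a difference of -1.59 (edgeR adjusted p = 1.39e-05).

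CD44, the cell-surface receptor for hyaluronan, has variable exons that are spliced in different combinations, and it made up 12 of the 17 events listed in both genotypes. All 12 were higher in set 1 in both. The exon at chromosome 11, 35196746 to 35196874, differed by 0.42 in MTAP-null and 0.17 in MTAP-WT in the authors' deposited table. ZFAS1, another host of small nucleolar RNAs, had an exon with -0.24 and -0.13 in the authors' deposited table. Of the 17 events, 16 went the same way (exact binomial p = 0.000275), but they came from 6 genes, 5 of which went the same way. The exception was a retained intron of MROH1, a protein with HEAT repeats, at 0.41 and -0.55 in the authors' deposited table, with at least 16.7 and 8.83 reads per library. CD44, ZFAS1 and MROH1 were named after their values were seen.

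**Figure D3:**
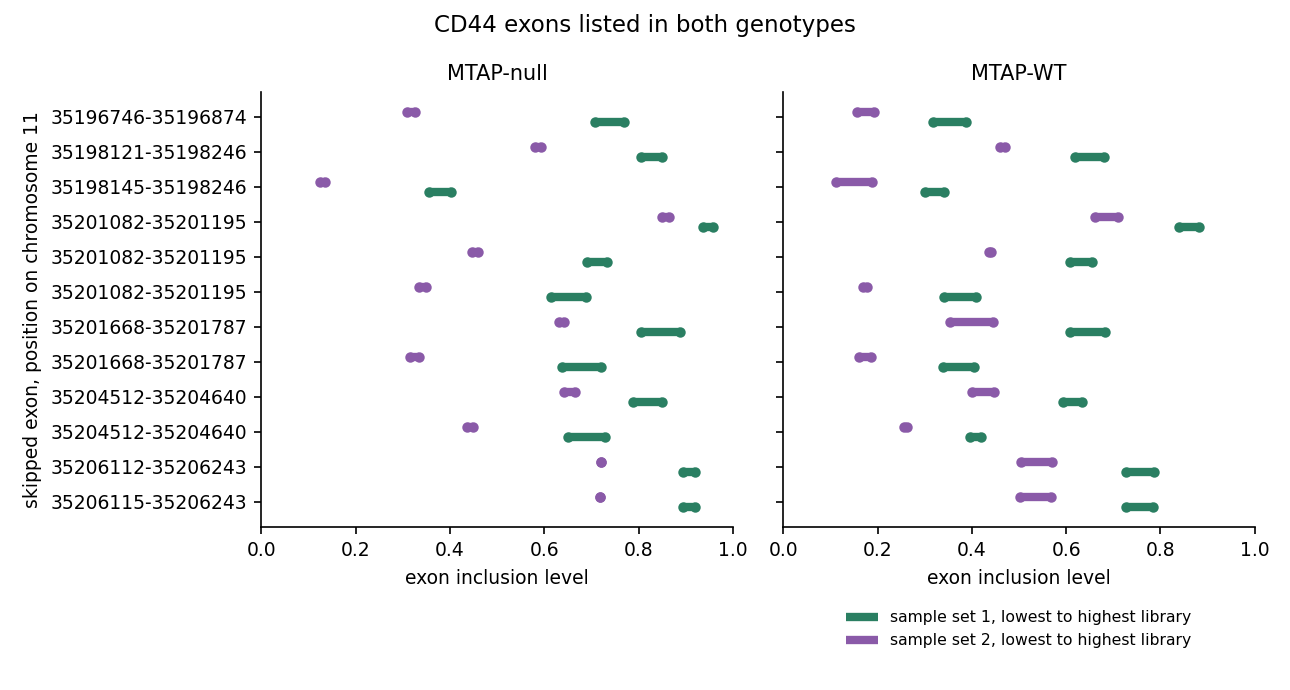
Inclusion levels (horizontal axis, 0 to 1, from the authors' deposited table) of the 12 CD44 skipped-exon events listed in both genotypes, with 1 line per event from the lowest to the highest of the 3 libraries of a set. Set 1 lies above set 2 in all 12 events of each genotype, at 0.707 to 0.769 against 0.308 to 0.326 for the first exon in MTAP-null; an exon position that appears again is an event with other flanking exons.

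The 2 methods listed different genes for the most part. Of the 51 rMATS retained introns in MTAP-null, 5 overlapped a listed intron feature, and 52 of 357 genes with events (14.6%) were in the intron table. In MTAP-WT 0 of 10 retained introns overlapped one and 2 of 73 genes were shared. Where an rMATS segment coincided with a listed intron feature, the signs of the set difference and of the usage change were equal in 15 of 15 MTAP-null pairs from 10 genes, RBM39 and TAB3 among them, and in 2 of 2 MTAP-WT pairs, both CD44. Equal signs are what AGI24512 as set 1 would give, and they argue against DMSO as set 1 for these 10 MTAP-null genes. In MTAP-WT they rest on 1 gene, CD44, whose listed feature has the position of a skipped exon. The headers do not name the sets, so the sets were left unassigned.

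Increased introns were long and seldom first in the transcript. In MTAP-null they were longer than the other annotated introns of the same gene in 434 of 690 genes (exact sign test p = 1.24e-11), with a median log2 difference of 0.53. In MTAP-WT this held in 51 of 78 genes (exact sign test p = 0.00877, median 0.78), but not among features with an adjusted p below 0.01 (p = 0.511) or with a change of at least 1 on the log2 scale (median -0.21). Increased features had a median width of 2478 bp against 1292 bp for decreased ones in MTAP-null (1159 and 79 genes, permutation p = 0.00091). In MTAP-WT the widths were 2883 and 714.5 bp (175 and 48 genes, permutation p = 4e-05). This comparison was not limited to features that match an annotated intron, so a feature may be part of an intron or lie in an exon. With 1 intron drawn per gene, 46 of 690 MTAP-null introns were first introns against 104.6 expected at random (permutation p = 1e-05, the smallest possible), and 84 were last against 83.9. In MTAP-WT 6 of 78 were first against 10.9 (permutation p = 0.122). The tables hold only introns named as detained, and the comparison is with all annotated introns of the gene.

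Skipped exons with a length divisible by 3, which keep the reading frame, made up 63 of 134 events higher in set 1 and 58 of 142 higher in set 2 in MTAP-null (Fisher's exact p = 0.332). In MTAP-WT they were 25 of 36 and 11 of 25 (Fisher's exact p = 0.0651). Among MTAP-WT events with at least 20 reads per library they were 21 of 23 and 6 of 14 (Fisher's exact p = 0.00232), but with each exon counted once the full comparison gave p = 0.274. The 12 CD44 events listed in both genotypes are all higher in set 1, divisible by 3 and above 20 reads. They are thus among the 21, and many of them share an exon, so that p-value rests largely on a single gene.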

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

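The tests of depth and of replicate noise, TMM scaling and the stricter settings of the odds ratio were chosen only after the results were seen. Genotype is tied to the clone, and to any batch of culture or sequencing, so no difference between the genotypes can be assigned to the loss of MTAP.

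At 17 of the 92 introns listed in both genotypes the effect of AGI24512 on the read count differed between MTAP-null and MTAP-WT in the drug-by-genotype test of edgeR, which is what brought them here. More positive in MTAP-null, in log2 units, were RCC1 with SNHG3 (1.40), ARHGAP29 (1.40), CPNE7 (1.48), TMEM181 (1.13), TMCC1 (0.86), DMKN (0.80), GALNT18 (0.68), ESPN (0.61) and ASPH (0.51). More positive in MTAP-WT were KRT8 (-1.59), RPLP0 (-0.90), TM9SF1 (-0.87), RPS14 (-0.77), RNF187 (-0.72), PAX8-AS1 (-0.55), RPL15 (-0.53) and IAH1 (-0.52). At KRT8, RPS14 and TMEM181 the read count went opposite ways in the 2 genotypes and passed in each. With TMM scaling KRT8 in MTAP-WT kept 0.25 without a call, while RPS14 in MTAP-WT turned to -0.25 and TMEM181 in MTAP-null to -0.31. Usage went opposite ways at KRT8, TMEM181, DMKN, ASPH, TMCC1 and AP1S1. Of 100 splits of the 12 libraries, 6 gave as many calls as the real labels, the real one included, with 49 as the highest other count. Splits that exchange genotypes within a treatment count genotype differences as drug effects, a structure of the libraries that such splits carry into their calls. The splits are thus no distribution without change, and they do not settle whether chance is excluded for the number of calls.

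A retained intron of MROH1 (chromosome 8, 144260545 to 144260676) went opposite ways in the rMATS tables. Its difference was -0.55 in MTAP-WT, with all set 1 levels under all set 2 levels, and 0.41 in MTAP-null, with the reverse, in the authors' deposited table. The difference between genotypes was not tested, and the lower bounds were 8.83 and 16.7 reads per library.

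The balance of increased against decreased introns also differed between genotypes, with an odds ratio of 3.84 in the direction of MTAP-null. It was 5.16 and 5.88 at an adjusted p below 0.01 and 0.001, but 1.38 (Fisher's exact p = 0.564) among introns with a change of at least 1 on the log2 scale, where MTAP-WT had 25.

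MTAP-null further had 6.004 times as many listed introns. At the shared introns the median ratio of raw counts, MTAP-null to MTAP-WT, was 1.013, and the deposited dispersion was larger in MTAP-WT at 45.7% of them. These introns passed in both genotypes and so are chosen for enough reads and low noise in each, which leaves depth and replicate noise open as explanations. Between libraries of a group the chi-square per degree of freedom, over different introns in each genotype, reached 3.77 (DMSO) and 4.09 (AGI24512) in MTAP-WT and 1.81 and 5.12 in MTAP-null. Depth, noise, clone or batch and an effect of MTAP cannot be told apart, because the labels give no further clone of either genotype and MTAP-WT counts for introns listed only in MTAP-null were not analysed here.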

How the results depend on the processing

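The settings for the read counts (mean filter, TMM, DESeq2, replicate block, left-out libraries), for the drug-by-genotype test, for the size of shared changes, for the odds ratio between genotypes, for the direction of shared introns against the increased shares and for the exon frame were chosen after the data were seen. Over 43 results, 192 of 254 alternatives kept the direction and the side of the threshold (among them the left-out libraries of rMATS, which could turn only signs), 3 were weaker, 1 stronger, 48 moved and 10 reversed. Where no construction explains a change, the cause was not tested.

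Stricter thresholds list fewer features by construction. Increased and decreased introns in MTAP-null were 855 and 63 at an adjusted p below 0.01, 504 and 45 below 0.001, 166 and 5 with a log2 change of at least 1, and 690 increased among features above the median count. In MTAP-WT they were 92 and 35, 40 and 21, 24 and 1, and 87 increased. Shared introns at an adjusted p below 0.01 in both were 51. At an FDR below 0.01 MTAP-null kept 170 SE, 33 RI, 19 A3SS, 36 A5SS and 19 MXE events, and MTAP-WT 40, 4, 1, 7 and 3. At a difference of at least 0.2 they were 174, 31, 23, 25 and 24 in MTAP-null, and 36 SE and 3 MXE in MTAP-WT. With genes counted MTAP-WT had 40 SE. With at least 20 reads it had 37 SE, 4 RI, 3 A3SS, 4 A5SS and 2 MXE; these counts use lower bounds of the reads.

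The share of events higher in set 1 crossed 50% in some settings, in no case with a p below 0.05. MTAP-null SE gave 52.4% at an FDR below 0.01 and 50.2% at 20 reads, and A3SS 56.5% at a difference of 0.2 and 51.5% by gene. MTAP-WT gave 42.5% for SE and 44.4% for RI by gene, 25% for RI and 75% for A5SS at 20 reads, and 100% for A3SS at an FDR below 0.01. The length difference of increased introns in MTAP-WT fell to 0.41 at an adjusted p below 0.01 and reversed to -0.21 at a log2 change of at least 1. Shared introns with the larger change in MTAP-null were 50 by read count. The odds ratio between genotypes was 1.38 at a log2 change of at least 1. The frame odds ratio in MTAP-WT was 14 at 20 reads, where many events are of CD44.

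Lists past the threshold for MTAP-null introns went from 3 to 0 at an adjusted p below 0.01 and 0 with only increased introns. The odds ratios moved less: 3.35 to 2.90 and 2.66 for splicing regulators, 3.07 to 2.95 and 2.78 for decay and export, and 0.53 to 0.51 and 0.56 for ZNF genes. Against genes listed by either genotype 0 passed (decay and export 0.80, regulators not finite), but nearly all of those genes are MTAP-null genes, so this background could not show an enrichment. For MTAP-WT introns 0 lists passed with only increased introns (ribosomal odds ratio 0). For MTAP-null events 3 passed at an FDR below 0.01 and 0 against genes listed by either genotype (methionine metabolism 0.5), with the same limit.

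TMM scaling gave 251 introns that rose and 253 that fell in MTAP-null and 60 and 68 in MTAP-WT; TMM sets the typical change near 0 by construction, so smaller changes turn and this says nothing about single genes. Of 102 named introns, 91 passed. With this shift 32 calls ended and 20 of the estimates turned. DESeq2 ended 6, leaving out 1 library 18, and the filter at a mean count of 10 ended 1. Turned by the shift in MTAP-null were SAT1 (-0.0244), XRCC3 (-0.28), TP53BP1 (-0.14), RECQL4 (-0.0542), DCLRE1C (-0.12), RBM5 (-0.22), CLK3 (-0.29), CLNS1A (-0.19), PUS7 (-0.21), METTL4 (-0.0489), YTHDC1 (-0.20), KAT8 (-0.57), RPL5 (-0.27), ZNF250 (-0.0042), WARS2 (-0.0269) and SARS (-0.0747), and in MTAP-WT ERCC8 (-0.0597), SNRNP27 (-0.20), HDAC7 (-0.0317) and RPS14 (-0.25).

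With 1 library left out, the introns that rose ranged from 1005 to 1281 in MTAP-null and 169 to 180 in MTAP-WT, and those that fell from 62 to 71 and 34 to 39. Drug-by-genotype calls ranged from 16 to 24. The listed rMATS events were not called again, only their signs recomputed, so the shares say little about stability: 48.6%, 86.3%, 48.6%, 64.3% and 61.5% in MTAP-null (SE, RI, A3SS, A5SS, MXE) and 59.0%, 50%, 11.1%, 42.9% and 20% in MTAP-WT. With the replicate block, MTAP-null had 1215 that rose and 72 that fell, MTAP-WT 178 and 37, and the drug-by-genotype test 17 calls. The equal numbers showed no pairing, with correlations of 0.07, 0.04 and 0.01 in MTAP-null and -0.12, -0.02 and 0.06 in MTAP-WT. No paired analysis was possible because of the rMATS tables' form: values within a cell are not tied to replicate numbers, so that block was not run.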

Other observations

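The tests of scaling, of the common gap and of small nucleolar RNA hosts were chosen only after the results were seen.

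GAS5, a growth-arrest transcript that hosts small nucleolar RNAs, showed the mirror image of MAT2A in MTAP-null cells. Its intron at chromosome 1, 173864705 to 173865228, had a usage log2 change of 0.43 in the authors' deposited table. Its normalised count fell from 1107 ± 60.1 to 579.6 ± 60.5 (SD, n = 3; edgeR adjusted p = 5.94e-06). TRIB3, a stress-induced pseudokinase, and NBPF1 had the same combination, with log2 changes of the read count of -0.90 and -1.18 and usage changes of 0.50 and 0.24 in the authors' deposited table. In all, 12 MTAP-null introns had higher usage and a fallen count, among them RBCK1, GTPBP2, P4HB and RPL10. The opposite combination was found, among others, at MAT2A, CEBPZ, AP1S1 and CEP290 in MTAP-null and at MAT2A and RPS14 in MTAP-WT, where TMM scaling, which lowers all listed introns about alike, turned the smaller changes (CEBPZ -0.59, AP1S1 -0.31, CEP290 -0.0867, RPS14 -0.25). These genes were named after their values were seen.

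Hosts of small nucleolar RNAs were over-represented in MTAP-null. They made up 38 of 1160 genes with a listed intron (3.28% against 0.99% of all annotated genes; Fisher's exact test, odds ratio 3.66, adjusted p = 6.02e-10), among them SNHG1, SNHG5, SNHG7, NOP56 and EIF5. Among genes with rMATS events they were 16 of 323 (odds ratio 5.397, adjusted p = 3.71e-07), with SNHG8, SNHG16, SNHG17, ZFAS1 and EIF4A2. In MTAP-WT 6 of 208 genes with introns were hosts (odds ratio 2.997, adjusted p = 0.0241) and 1 of 62 with events (adjusted p = 0.461). A host here was any gene with more than 1 exon that spans an annotated small nucleolar RNA on its strand. ASTN2, FHIT and PTPRM counted by this rule, while GAS5 was not among the 38. The expression of hosts was not measured. The background controlled neither for expression, nor for gene length, nor for which genes have an intron named as detained.

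Most MTAP-null introns were higher with AGI24512. Genomic DNA in the AGI24512 libraries is argued against, since 95.7% of the 1430 higher introns that were compared gained more reads per kb than the emptiest long features hold. A scaling factor common to a library cancels in the usage, which is relative to the same gene, so by construction it does not bear on the 93.5% of introns with higher usage, while the read counts do depend on it. Other splits of the libraries were too few to judge chance: in MTAP-null 1 of 10 splits, the real one, reached 1274 calls and the highest other had 0, and in MTAP-WT 1 of 10 reached 219 with 0 as the highest other. The treatment, which the design names, was not set against any other biological explanation.

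The MAT2A intron gained reads but lost usage in both genotypes. The gap between read count and usage had a median of 0.38 over the MTAP-null introns and 0.29 over the MTAP-WT introns. At MAT2A it was 1.71 and 1.70, a size reached by 11 of 1549 MTAP-null introns (0.71%) and 2 of 258 in MTAP-WT. This pattern was picked for its opposite signs, and the 2 measures differ in scale. A low share was thus largely built in, so it does not decide whether the gap is common to the listed introns. A single library is argued against, because the log2 change was at least 0.88 with any 1 library left out. The size of the rise depends on the scaling: TMM, which lowers all listed introns about alike, left 0.31 without a call in MTAP-null. A larger amount of MAT2A RNA with more complete removal of this intron may be the source, but the RNA of the whole gene was not analysed here.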
